A study of Homo sapiens with 7 samples.

How the data were processed

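VDR ChIPmentation libraries were made from THP-1 cells after 8 h with 100 nM 1,25D or with 0.1% ethanol, 3 per treatment, beside 1 input library with no peak list here. Per the labels' protocols, cells were crosslinked with formaldehyde, ChIPmentation was done with an antibody against VDR, and libraries were prepared with the NEBNext Ultra II DNA kit, barcoded with Nextera primers and sequenced on an Illumina HiSeq2000. The series' design text speaks of ChIP-seq or ChIPmentation, and each of these samples is described as ChIPmentation.

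Reads were aligned to hg19 (GRCh37) with Bowtie 1.1 and peaks were called with MACS2, per the submitters' processing notes, which list these tools without their settings. The MACS2 version, the use of the input as a control, the peak threshold and any removal of duplicate reads are not given in the sources used here. Each peak list belongs to 1 sample, so peaks were called per library and replicates could be compared. The lists hold the chromosome, start and end of each peak with 2 values, which are the peak's own. One is a fold enrichment, a ratio over the background that the authors' peak caller computed, per the file headers. The other is the authors' p-value, per the file headers. Its maximum was 0.00433 in 1,25D replicate 1, 0.00431 in EtOH replicate 1 and between 0.00978 and 0.00997 in the other lists, so both replicates 1 share a lower limit than the rest, and the lists differ in the weakest peak they hold. The results were therefore computed again with 1 highest p for all lists and within the lists of each limit. Whether the starts are counted from 0 or from 1 is not stated, so coordinates are printed as listed and a start may be off by 1 bp. A fold was used to describe, rank or filter peaks within its own list, and folds of a site were averaged over the lists of a treatment as a description. The mean 1,25D fold also served to group sites for 1 permutation test in the closing section. Sequencing depth is unknown, and no interval that needs counts is given. A peak missing from a list means that it did not pass the caller's threshold there, not that VDR was absent.

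The lists run in the order of chromosomes 1, 10 to 19, 2, 20 and on, 3 to 9 and X, and 3 of them ended in mid-line as used here. The incomplete last line was left out. All 6 libraries were compared over the first part, up to the last complete peak of the shortest list, and the 5 longer lists over the second part, up to the point where the next list ended. What follows is covered by the 3 complete lists, of which 1 is from 1,25D, and up to chromosome 6 at 86580665 also by EtOH replicate 3, which was left out of the counts there. The comparisons of peak numbers, site counts and overlap with their splits of the libraries, the settings of fold 5, equal list length, centres, 50% overlap, left-out libraries and the replicate block, and the rule for named sites were fixed before the data were examined. This division and all other comparisons, settings and tests were chosen once the lists had been seen, among them the rank comparison, the recovery of sites by fold, the random offsets, the windows, the repeated values, the thresholds of fold 10, fold 20 and p 1e-10, the 2 settings on the highest p and every test of an explanation.

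Peaks were merged into sites where they shared at least 1 bp across the 6 lists, and the highest fold of a list at a site was taken as its fold there. Peak numbers were compared as log2 values with a two-sided exact permutation test over the 20 assignments of the labels, whose smallest p is 0.1. Sites were counted by the number of lists of each treatment that called them, and the counts and the Jaccard index were computed again for each of the 10 splits of the libraries into 3 and 3. Coincidental overlap was estimated by moving each list by a random offset, 100 times. No test across single sites was run, because absence and presence in 3 against 3 libraries cannot give a p below 0.1. The named sites are the 10 with the highest mean within-list percentile of fold among the sites in all 1,25D and no EtOH lists, in all EtOH and no 1,25D lists, and in all 6. The sites with the widest gap in rank and the sites of the second part and of the rest of the genome were chosen after their values were seen.

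The gene table at hand was of GRCh38: the furthest peak on chromosome 1 ended at 249239892, beyond its last gene on that chromosome at 248937099. Coordinates were not converted. The tests planned for a genome or annotation of hg19, which were the share of peaks with a VDR motif of half-sites 3 bp apart, the share at promoters, peaks near 13 gene lists and the naming of genes near sites, were therefore not run here. No 2 lists shared an identical line. No column of another sample was used (0 columns).

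The merging and ranking steps were tested on simulated lists. Among 32724 simulated sites, 497 fell in all 1,25D lists only (500 planted), 50 in all EtOH lists only (50 planted) and 300 in all 6 (300 planted). These are counts per class and were not matched to the planted positions. Each planted site was put into every list of its class and the other peaks were placed at random. Nearly full recovery therefore followed from the design. Sites missed by some lists of a class and peaks gathered in windows were not simulated. Of 1192 simulated shared sites, simulated once per size of change, the rank comparison separated 129 of 200 with a 1.5-fold rise, 182 of 200 with a 2-fold rise and 197 of 200 with a 3-fold rise. In lists simulated with no change at any site it separated 113 of the 1192. All simulated lists had the spread between the 1,25D lists. The EtOH lists agreed less in rank, so the shares separated may not hold for the data. The alternatives tried were stricter folds, lists reduced to the 3647 strongest peaks each, centres within 200 bp or at least 50% of the shorter peak in place of 1 bp, leaving out each library in turn, leaving out chromosome 1, the settings on the highest p and a replicate block. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.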

Results

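The series measured where the vitamin D receptor (VDR) sits on the genome of THP-1 cells, a human line derived from an acute monocytic leukaemia. VDR is a nuclear receptor whose ligand is 1α,25-dihydroxyvitamin D3, called 1,25D here. Cells were treated for 8 h with 100 nM 1,25D or with the solvent, 0.1% ethanol (EtOH), and VDR-bound DNA was recovered by ChIPmentation, a chromatin immunoprecipitation in which a transposase adds the sequencing adapters. There were 3 libraries per treatment, and an input library that was not analysed here. The labels do not say that the replicates came from separate cultures. The spread between libraries, which the p-values that compare libraries measure, may therefore be technical.

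Each library had its own list of peaks, with the authors' fold enrichment and p-value for each peak. Read counts are not given in the lists, so the sequencing depth behind a peak is unknown. The lists in hand held 15262, 3647 and 8620 peaks for 1,25D replicates 1 to 3 and 15974, 33820 and 11895 peaks for EtOH replicates 1 to 3. As used here, 3 of these lists stopped in mid-line: 1,25D replicate 2 on chromosome 16 after position 50293713, 1,25D replicate 3 on chromosome 5 after 90175161 and EtOH replicate 3 on chromosome 6 after 86580665. The comparison of all 6 libraries was therefore limited to the first part of the lists, which is chromosomes 1 and 10 to 15 and chromosome 16 up to 50293713. Coordinates are those of the lists, in hg19, and sites are named by position only, since no gene annotation of that build was used here.

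The first comparison asked how many places the VDR antibody enriched with and without the hormone, and the answer depended on how strong the peaks were. Strong peaks were several times as many after 1,25D: at a fold enrichment of 10 or more there were 231 ± 22.5 per 1,25D library and 38.7 ± 6.35 per EtOH library (mean ± SD, n = 3 each), a ratio of geometric means of 6.01. At a fold of 20 or more there were 47 ± 8.89 against 7 in each of the EtOH libraries, a ratio of 6.63, and at a fold of 5 or more 823 ± 71.5 against 255 ± 56.1, a ratio of 3.28. Peaks with a p-value of 1e-10 or less numbered 523 ± 60.1 after 1,25D and 120 ± 14.8 after EtOH, a ratio of 4.36. Peaks of any strength went the other way, with 4425 ± 778 per 1,25D library and 7430 ± 3374 per EtOH library, a ratio of 0.627.

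The lists therefore differed in make-up. Peaks with a fold of 5 or more formed 14.5%, 22.5% and 20.3% of the 1,25D lists and 5.39%, 2.57% and 3.32% of the EtOH lists. The highest fold in a list was of similar size in both groups, at 63.8, 43.3 and 51.9 for 1,25D and 51.7, 48.4 and 38.6 for EtOH. Peaks were on average 260 ± 41.2 bp long in the 1,25D lists and 189 ± 9.19 bp in the EtOH lists (mean ± SD of the library means, n = 3). In each of these comparisons of peak number or length the 1,25D libraries did not overlap the EtOH libraries, which gives a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. EtOH replicate 2 alone listed 11317 peaks in the first part, against 5251 and 5722 in the other EtOH libraries and 5203, 3647 and 4424 in the 1,25D libraries. The lists of both replicates 1 ended at a lower highest p than the rest. Between these 2 libraries the ratio of peak numbers was 0.991 for all peaks, 2.66 at a fold of 5 or more and 5.94 at 10 or more, and over the other 4 libraries it was 0.499, 3.65 and 6.05. With 1 highest p for all lists the ratio for all peaks was 0.641 with an exact permutation p of 0.2.

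**Figure D1:**
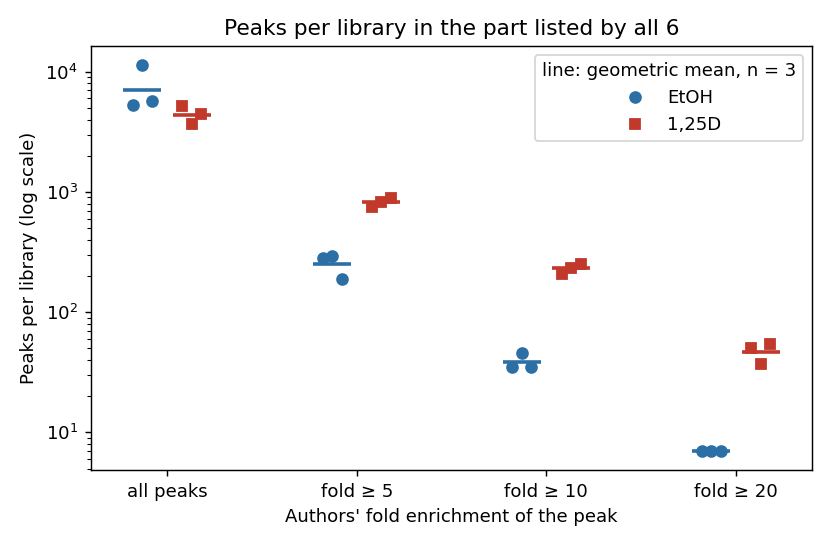
Number of peaks per library (log scale) in the part of the genome listed by all 6 libraries, for all peaks and for peaks above 3 thresholds of the authors' fold enrichment. Points are libraries and lines geometric means (n = 3); the 1,25D libraries lie below the EtOH libraries for all peaks and above them at folds of 5, 10 and 20 or more.

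The second comparison asked which sites were called with the hormone, without it or in both, after peaks sharing at least 1 bp had been merged into sites. A total of 492 sites had a peak in all 3 1,25D lists and in no EtOH list, whereas 11 sites had a peak in all 3 EtOH lists and in no 1,25D list. Another 298 sites were called in all 6 libraries. The 1,25D-only sites were spread over all 8 chromosomes compared, with 160 on chromosome 1, 75 on chromosome 10 and 69 on chromosome 12, while the EtOH-only sites lay on chromosome 1 (8 sites) and chromosome 10 (3 sites). Of the 1217 sites called in every 1,25D library, 40.4% were in no EtOH list, 24.5% were in all 3 and the remaining 427 sites were in 1 or 2. Of the 342 sites called in every EtOH library, 87.1% were also called in every 1,25D library.

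The 1,25D-only site that ranked highest within its lists was on chromosome 12 at 102248448 to 102249021, where the authors' fold enrichment was 17.8 ± 1.60 (mean ± SD over the 1,25D lists, n = 3 here and below). The next was on chromosome 11 at 33915105 to 33915901, with a fold of 14.2 ± 1.42. Chromosome 1 held a site at 233462998 to 233463591 with a fold of 11.8 ± 2.25, a site at 234658170 to 234658782 with 12.5 ± 4.06 and a site at 154453372 to 154453923 with 10.3 ± 0.377. On chromosome 12 the site at 4322431 to 4323049 had a fold of 11.4 ± 2.17, the site at 96447905 to 96448411 had 11 ± 0.843 and the site at 104680486 to 104681357 had 9.95 ± 1.04. The top 10 were completed by chromosome 16 at 31264953 to 31265404, with 10.3 ± 0.50, and chromosome 14 at 92852954 to 92853372, with 10.2 ± 0.310. Over all 492 sites the median fold was 4.86 (quartiles 4.14 and 6.04), and 13 sites had a mean fold of 10 or more.

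The EtOH-only sites were weak. The highest-ranked was on chromosome 1 at 239229982 to 239230456, with a fold of 4.998 ± 1.29 in the EtOH lists. It was followed by chromosome 10 at 80409320 to 80409706, with 3.82 ± 0.0960, chromosome 1 at 241253832 to 241254609, with 4.17 ± 1.42, and chromosome 1 at 41406251 to 41407259, with 4.24 ± 2.04. The other named sites on chromosome 1 began at 145003350 (fold 3.36 ± 0.347), 174326863 (3.23 ± 0.495), 219372285 (2.98 ± 0.430) and 40668156 (2.77 ± 0.405). Those on chromosome 10 began at 42395597 (3.03 ± 0.193) and 42387670 (2.53 ± 0.557). The site at 41406251 began soon after a site called in every list of both treatments, at 41405208 to 41406025 (mean 1,25D fold 12.7). The site at 145003350 followed another such site, at 144997264 to 145001001 (16.1). Those at 42387670 and 42395597 lay on either side of such a site at 42390844 to 42391745 (2.59). The other named sites lay further from any such site. Whether these neighbours are separate sites was not tested. The median fold of the 11 sites was 3.23, and none had a mean fold of 5 or more.

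The shared sites named here are those with the highest mean percentile over the lists of both treatments. The site on chromosome 1 at 119382943 to 119384860 had the highest fold of any shared site in all 6 lists, at 53.0 ± 10.3 in the 1,25D lists and 46.3 ± 6.80 in the EtOH lists. Chromosome 12 at 26450856 to 26452271 had folds of 45.7 ± 7.73 and 33.8 ± 1.62, and chromosome 11 at 73966484 to 73968237 had 39.4 ± 5.80 and 39.0 ± 7.86. The site on chromosome 1 at 79445380 to 79447313 had a fold of 42.8 ± 7.83 after 1,25D and 15.3 ± 2.06 after EtOH, and the site on chromosome 1 at 47152964 to 47154840 had 28.7 ± 3.45 and 22.8 ± 2.08. The other named shared sites, on chromosome 1 at 175489834 to 175491533, chromosome 10 at 70825174 to 70826329 and 73698078 to 73699021, chromosome 12 at 94241321 to 94242700 and chromosome 14 at 89823967 to 89824757, had folds of 29.4 to 40.0 in the 1,25D lists and 12.3 to 23.6 in the EtOH lists. Folds come from separately processed lists and were not tested against each other. Shared sites, which merge peaks of more lists and are longer in part for that reason, had a median length of 829 bp against 438 bp for the 1,25D-only sites.

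When every list was moved along the genome by its own random offset of up to 1 Mb, 100 times over, on average 0.18 sites (2 at most) fell in all 1,25D lists and no EtOH list, 0.53 (3 at most) in all EtOH lists and no 1,25D list, and none in all 6. At 2 of 3 libraries, 531 sites were called in both groups, 1128 were called in 1,25D and in no EtOH list, against 42.2 with moved lists, and 304 were called in EtOH and in no 1,25D list, against 102.7. Most sites were called in a single library: 26034 of 28993 sites (89.8%), of which 18967 were in an EtOH list and 7067 in a 1,25D list. The 1,25D-only count was 915, 577 and 636 without 1,25D replicates 1, 2 and 3, where fewer lists have to agree. With weaker peaks dropped from every list before merging, it was 292 at a fold of 5 or more and 119 at 10 or more. Sites counted this way can have a weaker EtOH peak, since only 13 of the 492 had a mean fold of 10 or more. The EtOH-only count was 110, 99 and 117 without EtOH replicates 1, 2 and 3, where only 2 EtOH lists have to agree. It was 0 at a fold of 5 or more, and 3 to 6 with equal list lengths, with a 50% overlap or without chromosome 1. Over the 4 libraries other than replicates 1, 968 sites were 1,25D-only and 120 EtOH-only, or 147 and 0 among peaks with a fold of 10 or more. Between the replicates 1 the numbers were 4658 and 4695, or 173 and 0 among such peaks. Here too, sites counted at a fold of 10 or more can have a weaker peak in the other treatment.

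**Figure D2:**
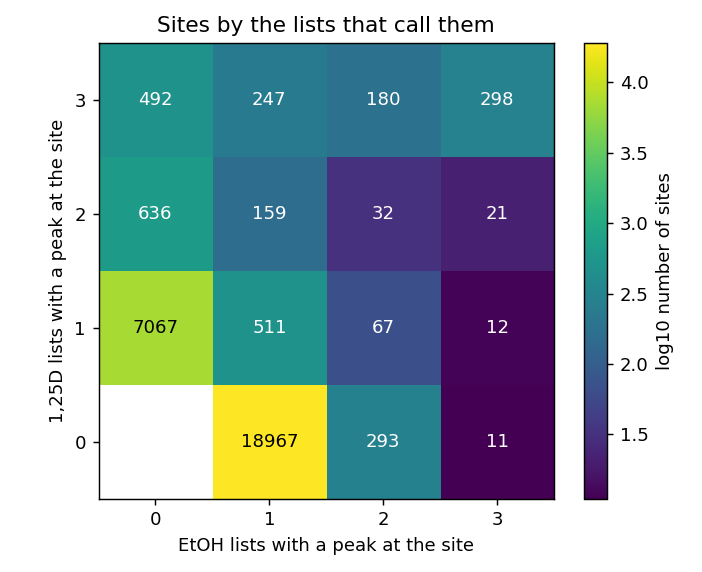
Number of sites by how many 1,25D lists (vertical axis, 0 to 3) and EtOH lists (horizontal axis, 0 to 3) have a peak there; the colour is log10 of the number. Of the sites in all 3 lists of one group and in none of the other, 492 were 1,25D-only and 11 were EtOH-only, and 298 sites were in all 6 lists.

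The single-library sites were unevenly spread. Chromosome 1 held 11417 of the 26034, a share similar to its 12683 of the 28993 sites of any kind. Of 195 windows of 5 Mb with a site in the first part, the window of chromosome 1 at 190 to 195 Mb held 478 single-library EtOH sites and 153 single-library 1,25D sites and the window at 215 to 220 Mb held 468 and 166, against medians of 78 and 27. Sites called in all 3 1,25D lists were most numerous at 40 to 45 Mb of chromosome 1, with 50 sites against a median of 5 per window and 19 in the next highest window.

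**Figure D3:**
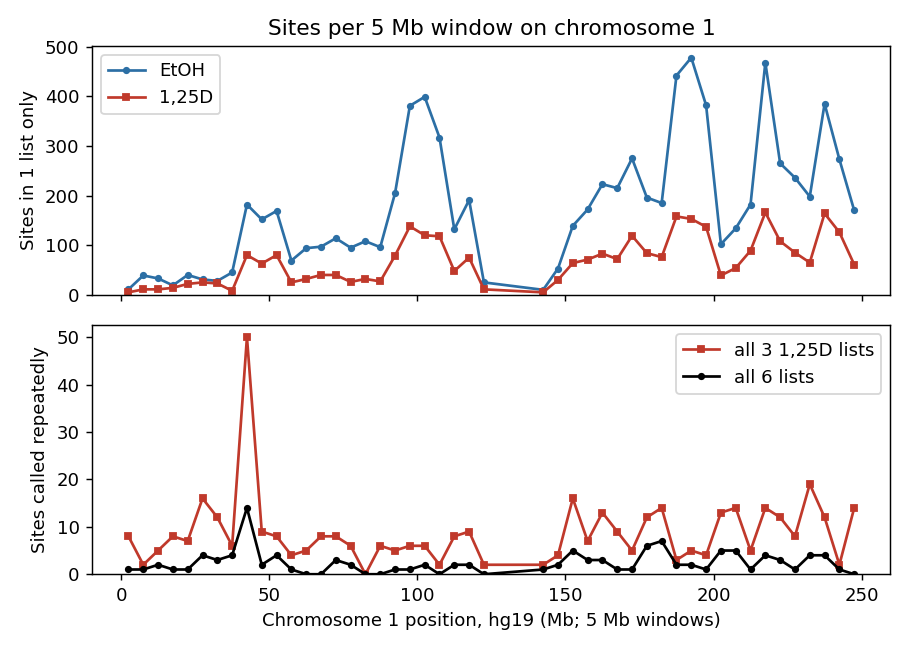
Sites per 5 Mb window along chromosome 1 (horizontal axis, hg19 position in Mb), with sites called in a single EtOH or 1,25D list in the upper panel and sites called in all 3 1,25D lists or in all 6 lists in the lower panel. Single-library sites had their highest count at 190 to 195 Mb for EtOH (478) and at 215 to 220 Mb for 1,25D (166), and sites in all 3 1,25D lists at 40 to 45 Mb, with 50 sites.

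Libraries of the 1,25D group shared more sites with each other than any other pairing did. A pair of 1,25D lists shared a mean of 39.9% of the sites of the smaller list (range 30.6% to 49.9% over 3 pairs), with a mean Jaccard index (shared sites over all sites of the pair) of 0.215. A pair of EtOH lists shared 9.97%, with a Jaccard index of 0.0391, which was less than a 1,25D list shared with an EtOH list (15.1%, range 10.5% to 19.7% over 9 pairs, Jaccard index 0.0602). The mean within-treatment index exceeded the mean between-treatment index by 0.0669, and the highest value in any other of the 10 splits of the libraries into 3 and 3 was 0.0162. The real split ranks first of 10, an exact permutation p of 0.1, the smallest possible. The difference was 0.0386, 0.0122 and 0.0177 without 1,25D replicates 1, 2 and 3, where 1 pair of 1,25D lists is averaged with 3 pairs of EtOH lists. It was 0.107 to 0.116 without an EtOH replicate and 0.278 at a fold of 5 or more.

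Whether a 1,25D site was found in other libraries followed its strength. Sites with a fold of 12 to 20 in a 1,25D list were all found in both other 1,25D lists, 95.4% of them were found in at least 1 EtOH list and 69.0% in all 3 EtOH lists (means of the 3 1,25D lists). At a fold of 8 to 12 the shares were 98.9%, 77.5% and 38.3%, and at 5 to 8 they were 81.5%, 50.9% and 14.4%. At a fold of 3 to 4, 10.2% of sites were in both other 1,25D lists, 14.4% in at least 1 EtOH list and 1.07% in all 3. Sites with a fold of 20 or more in a 1,25D list were without exception present in at least 1 EtOH list, and 91.2% were in all 3. In the opposite direction, EtOH sites with a fold of 8 to 12 were all in at least 1 1,25D list and 99.1% were in all 3, on 38 to 43 sites per list. At a fold of 5 to 8, 75.5% of EtOH sites were in all 1,25D lists and 63.8% in both other EtOH lists, and at 3 to 4 the shares were 3.67% and 1.71%.

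**Figure D4:**
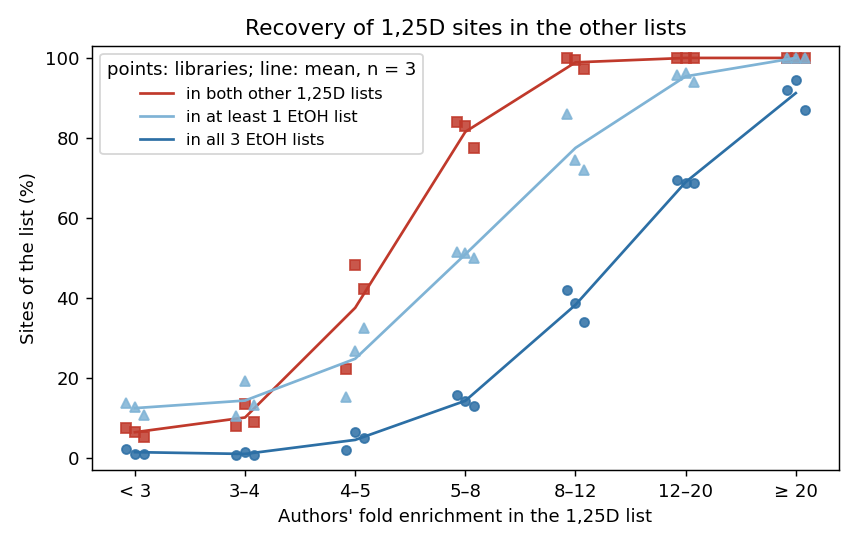
Share of the sites of a 1,25D list (vertical axis, %) found in both other 1,25D lists, in at least 1 EtOH list and in all 3 EtOH lists, by the authors' fold enrichment in that list (horizontal axis). Points are the 3 1,25D libraries and lines their means; at a fold of 8 to 12 the means were 98.9%, 77.5% and 38.3%.

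The order of the 298 shared sites by fold was then compared between treatments, a comparison chosen after the site counts were seen. Sites were ranked within each list from 1, the highest fold, to 298. At 134 sites (45.0%) the ranks of the 3 1,25D lists did not overlap those of the 3 EtOH lists, where chance gives 10%, or 29.8 sites. Of these, 62 ranked higher in every 1,25D list than in any EtOH list, and 72 ranked lower. The sites that ranked higher had a median fold of 18.9 in the 1,25D lists and 5.21 in the EtOH lists, and those that ranked lower had 8.38 and 7.39.

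Among these, the widest gap upwards was on chromosome 15 at 35638906 to 35639625, with a mean rank of 30 in the 1,25D lists (fold 23.1 ± 2.85) and 230 in the EtOH lists (4.12 ± 0.437). Chromosome 12 at 93523845 to 93525119 followed, with mean ranks of 33 and 224, then chromosome 11 at 121758039 to 121758872, with 91.5 and 259, and chromosome 13 at 99931607 to 99932534, with 50.3 and 209. Chromosome 14 at 93540424 to 93541148 had mean ranks of 74 and 227. The widest gap downwards was on chromosome 11 at 110551284 to 110552495, with a mean rank of 247 in the 1,25D lists (fold 5.24 ± 0.770) and 114 in the EtOH lists (6.65 ± 1.58). Next were chromosome 1 at 162149232 to 162150090, which ranked 123 places lower on average in the 1,25D lists, chromosome 10 at 116129939 to 116131017, with mean ranks of 202.5 and 81, and chromosome 11 at 128326028 to 128327560, with 217 and 96.7. Ranks are relative, so a site can rank lower because others rank higher. The count of sites with separate ranks was 67 for peaks with a fold of 5 or more, where fewer sites are shared. It was 83 without chromosome 1, which held 113 of the 298 shared sites. It was 211 without EtOH replicate 1 and 251 of 422 without either replicate 1. There fewer libraries have to be separate, and chance separates more than 10% of sites.

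**Figure D5:**
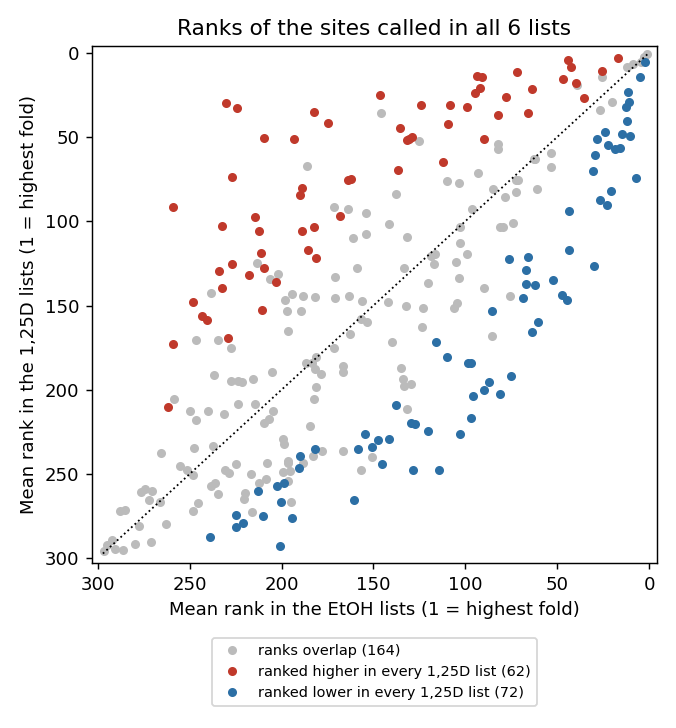
Mean rank by fold of the 298 sites called in all 6 lists, in the EtOH lists (horizontal axis) and in the 1,25D lists (vertical axis), with rank 1, the highest fold, at the top right. Red sites (62) ranked higher and blue sites (72) lower in every 1,25D list than in any EtOH list; the dotted line marks equal ranks.

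The same comparison was made in the second part of the lists, from the rest of chromosome 16 to chromosome 5 at 90175161, where 5 libraries remain (1,25D replicates 1 and 3, and all EtOH replicates). Here 627 sites were called in both 1,25D libraries and in no EtOH library, 2 in all 3 EtOH libraries and no 1,25D library, and 311 in all 5. The highest number of sites found in any other pair of the 5 libraries and in none of the rest was 102, over 10 pairs. The same 5 libraries had 577, 13 and 301 such sites in the first part, with 122 as the highest other pair. In both parts 2 lists had to agree for a 1,25D-only site and 3 for an EtOH-only site, so these counts were not equally strict. With 2 lists of each treatment in the first part, those other than replicates 1, there were 968 1,25D-only and 120 EtOH-only sites. The 1,25D-only site that ranked highest here was on chromosome 20 at 34791864 to 34792488, with a fold of 19.0 ± 0.686 (n = 2), followed by chromosome 3 at 48595949 to 48596566, with 13.6 ± 1.20, and chromosome 3 at 124318223 to 124318838, with 13.1 ± 1.55. Among the sites in all 5 lists, chromosome 2 at 231281025 to 231282338 had folds of 50.1 ± 4.0 (1,25D, n = 2) and 33.1 ± 2.15 (EtOH, n = 3), and chromosome 18 at 75929113 to 75930013 had 52.7 ± 3.67 and 24.7 ± 1.84. Peaks with a fold of 10 or more numbered 204 and 269 in the 1,25D lists and 39, 41 and 40 in the EtOH lists. Peaks of any strength numbered 4230 and 4196 against 3997, 10052 and 4667, a ratio of geometric means of 0.736 with an exact permutation p of 0.7.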

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

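What would decide the tests of list length, of rank agreement and of other splits of the libraries was written down after their results were seen, although the counts at equal list length and in other splits were planned; for the tests of peak width, of a uniformly weaker enrichment at the 1,25D-only sites and of regional background it was written before.

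The part of the genome after chromosome 5 at 90175161, which no comparison used, also held strong 1,25D peaks. There 1,25D replicate 1 listed 191 peaks with a fold of 10 or more, above the 30 and 41 of EtOH replicates 1 and 2, on 5829, 6726 and 12451 peaks of any strength. Of these 191 sites, 33 were in neither of these EtOH lists and 120 in both; EtOH replicate 3, whose list ends within this part on chromosome 6 at 86580665, was left out. The highest-ranked in 1,25D replicate 1 and in neither of the 2 complete EtOH lists was on chromosome 7 at 148281186 to 148281772, with a fold of 21.6, followed by chromosome 8 at 25202976 to 25203354, with 19.5. With 1 library of 1,25D the difference has no replicate check.

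For the 492 1,25D-only sites, the tables argue against wider 1,25D peaks, since with peak centres in place of overlap the count was 504, with 59 in the highest other split. Unequal list length is no explanation either, because the longer EtOH lists would lower the count, and at equal length it was 518, with 38 in the highest other split and 4 in the EtOH direction. A uniformly weaker EtOH enrichment stays open: all 3 EtOH libraries missed 492 of the 1217 sites, above the 339 (range 313 to 363) of 1000 permutations among sites of similar 1,25D fold, which met the bound written before, but that bound took the 1,25D fold as free of error, and the standard error of its log2 mean (0.17) exceeds the median width of the 48 strata (0.042), a limit raised after the result was seen. Of 10 splits, 1 gave as many sites (the real one; highest other 54), 5 gave at least the 11 EtOH-only sites (highest other 54) and 1 gave as large an overlap difference (0.0669; highest other 0.0162), and 10 splits are too few to give a share under 0.05. Chance, weaker EtOH enrichment, sequencing depth and the control used for each list stay open beside a response of VDR to its ligand, for which the design gives no separate test.

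For the 134 shared sites with separate ranks, 1 of 10 splits gave as many (the real one, highest other 26), again too few to judge chance. A site without tied ranks is separate in only 1 of the 10 splits. The 134 sites of the real split therefore lower the counts of the others, and the 26 is no independent comparison. A uniformly weaker EtOH enrichment would keep the order of sites. The rank correlation between treatments (0.605) over the geometric mean of those within them (0.921 for 1,25D, 0.702 for EtOH) would then be near 1. The ratio was 0.752 (95% bootstrap interval over sites 0.685 to 0.808), which is lower. This interval holds no spread between libraries. Only sites called in every list were ranked, which leaves out weaker EtOH folds, so a uniformly weaker enrichment is not excluded. Regional background would place sites that rank lower after 1,25D in windows with more single-library peaks. Their windows held a median of 102, which was 0.816 times the median for sites that rank higher. The permutation p over sites was 0.244 and the 95% bootstrap interval over sites 0.610 to 1.08, below the 1.5 set before as the bound. Sites in 1 window share its value and are not independent, and a small excess is not excluded. Depth, chance, a uniformly weaker EtOH enrichment and a smaller part of regional background stay open, beside a response to the ligand that differs from site to site.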

How the results depend on the processing

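The settings of fold 10, fold 20, p 1e-10, the second part, the highest p and leaving out chromosome 1, and every setting of the rank comparison, were chosen after the data were seen. The ratio of peak numbers, 0.627 for all peaks, reversed at a fold of 5 (3.28), 10 (6.01) and 20 (6.63) and at p 1e-10 (4.36), stayed at 0.544 to 0.799 with each library left out (exact permutation p of 0.1 to 0.4) and was 0.736 in the second part. With 1 highest p for all lists every result stayed within 1.5 times its value (0.641, 484, 10, 525, 0.0712 and 133 for peak numbers, 1,25D-only, EtOH-only, 2 of each group, overlap and ranks). Over the 4 lists of the higher limit, where fewer lists have to agree, there were 968 1,25D-only sites, 120 EtOH-only sites and 251 separate ranks, with a peak ratio of 0.499. The 1,25D-only count (492) was 292 at a fold of 5 and 119 at 10, with weaker peaks dropped from every list first. Sites counted this way can have a weaker EtOH peak. Of the 492, 220 had a mean 1,25D fold of 5 or more and 13 of 10 or more. The count was 535 to 915 with a library left out (915 without 1,25D replicate 1), where fewer lists have to agree. It was 332 to 518 with equal lengths, centres, 50% overlap, 1 highest p or no chromosome 1. The 11 EtOH-only sites became 0 at a fold of 5 and at 10, 4 with equal list lengths, 6 with a 50% overlap, 3 without chromosome 1 and 13 to 117 with a library left out (110, 99 and 117 without EtOH replicates 1, 2 and 3); the cause of the fall at equal lengths and at 50% overlap was not tested. Sites in at least 2 libraries of each group (531) became 175 at a fold of 5, and were 355 to 525 in the other alternatives. Separate ranks (134) became 67 at a fold of 5 and 83 without chromosome 1, which held 113 of the 298 shared sites. They were 150 to 211 with a library left out (211 without EtOH replicate 1), where chance separates more sites. The overlap difference stayed above 0 in all 13 alternatives (0.0122 to 0.278), with the lowest value without 1,25D replicate 2. Under centres and under 50% overlap, 10 and 10 of the 10 named 1,25D-only sites kept their class, 8 and 10 of the shared and 9 and 4 of the EtOH-only sites. Of the 10 named EtOH-only sites, 0 kept their class at a fold of 5, 4 with equal list lengths, and 10, 8 and 9 without EtOH replicates 1, 2 and 3.

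With a replicate block the ratio of peak numbers was 0.627 with a sign-flip permutation p of 0.25, the smallest that 3 pairs allow, and the overlap difference without same-numbered pairs was 0.0672. Deviations of same-numbered libraries correlated at 0.042, -0.0091 and 0.031 over 2959 sites, none above 0.1, so the numbers were not taken to pair the samples, although both replicates 1 share a lower highest p (0.00433 and 0.00431) than the other lists. The motif, promoter and gene list tests with their alternatives were not run, and a restriction to autosomes and X leaves the first part, which is autosomal, as it is. With depth unknown, a difference in depth between libraries cannot be taken out of any count.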

Other observations

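The windows and the repeated values were examined, and the test of weak binding chosen, only after the results were seen; the test of read depth was written down before its result.

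The window at 40 to 45 Mb of chromosome 1, with 50 of the 1217 sites called in all 3 1,25D lists, also held 17 of the 1,25D-only sites and 14 of those in all 6 lists, the highest of any window in both cases, and 16 of the 50 lay between 40.5 and 41 Mb. The 50 sites had a median fold of 3.95 (quartiles 2.87 and 5.36) against 5.74 (4.48 and 8.45) at the 1167 sites elsewhere. The EtOH-only sites on chromosome 1 at 41406251 to 41407259 and 40668156 to 40668554 lay in the same window.

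Sites called in a single library were densest in other windows. The window at 40 to 45 Mb was also above the median for them. It held 182 single-library EtOH sites and 80 single-library 1,25D sites, against medians of 78 and 27. Across windows the Spearman correlation of single-library sites between the treatments was 0.877, and between any 2 lists it was 0.638 to 0.885; windows are not independent replicates.

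Binding too weak to be called more than once might give such a pattern. Single-library sites followed the sites called in all 1,25D lists with a correlation of 0.160. The latter sites were few, with a median of 5 per window, and weak binding need not follow them. The correlation therefore cannot decide whether weak binding gave the pattern. Regional read depth, as from extra copies of a region in this line, could give the pattern too. Its test, the correlation of single-library sites per window with the median -log10 p at a fold of 3 to 4, gave -0.316 to 0.0717 over the 6 lists, under the bound of 0.1 set beforehand as evidence against it. That bound was set aside after the result was seen, because 70.0% to 96.6% of those peaks sit at a pair of fold and p-value that recurs at least 10 times in the list. If p then varies little at a given fold, the test cannot detect read depth. How far p varies at a given fold was not measured, so read depth was not told apart from other explanations.

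Repeated pairs of fold and p-value made up most of each list. Pairs that occur at least 10 times covered 76.6%, 60.5% and 69.8% of the peaks of 1,25D replicates 1 to 3 and 84.6%, 91.2% and 85.7% of those of EtOH replicates 1 to 3. At a fold of 8 or more they covered 11.3%, 6.05% and 7.75% in the 1,25D lists and none in the EtOH lists.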
